A study of Mus musculus with 2 samples.

How the data were processed

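The series holds 2 two-channel microarrays of mouse CD8+ T cells, each hybridised with total RNA of cells after 1 and after 2 stimulations, per the labels. The deposited table gives 1 signed value per probe and array, to 2 decimals, and was used as log2 ratios of the 2 channels. How the authors made these values (scanner, background correction, normalization, filters, genome or annotation) is not given in the sources used here. The deposited log2 ratios were centred close to 0 on each array, with medians of 0.01 and 0.02 and means of -0.0023 and -0.0022, so a general shift of all genes between the 2 stages would not be seen. Base 2 is an assumption: read as base 10, the largest value would be a ratio of 15488, while natural logs are not excluded by the values. The direction of the ratio and the dyes are not stated, and scanner intensities, spot flags and dye-swapped arrays were not used here. The 2 columns were compared before averaging and were not copies, since 248 of the 21427 probes with both values were equal.

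Of 21919 probes, 340 had no value on array 1, 300 had none on array 2 and 148 had none on either. Probes were named from the platform's annotation table: 15998 had 1 gene symbol, 288 had several and 5633 had none. The Entrez ID of 15799 of the singly named probes was found in a RefSeq gene table of the mouse, where 0 had another symbol. No genome was used, so probe positions are not given. Probes with 1 symbol and both values covered 14150 genes.

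The comparison was fitted with limma 3.58.1 in R 4.3.3, as an intercept over both arrays tested against 0 (two-sided), with moderated variances and Benjamini-Hochberg adjustment over 21427 probes at 0.05. Each probe has 1 residual degree of freedom, and the prior added 3.43. The median half-width of the 95% confidence interval of a mean log2 ratio was 0.396. A rule of size, at least 2-fold from 1 on both arrays on the same side, was applied beside the test. Gene lists (21, with 513 distinct symbols) were tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 mean value per gene, for lists with at least 5 measured genes, with adjustment over the 21 lists; fry and camera with an estimated correlation were alternatives. Over all 14150 genes, 29.6% were positive and 33.6% negative on both arrays, and the median was -0.02. The median of each list was also placed among 10000 random lists of the same size, which could not be matched on expression without intensities.

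Named genes followed a rule: on each side the 12 genes with the largest mean among those at least 2-fold on both arrays, every list member at least 2-fold on both arrays, and a fixed set of T cell genes whatever their value. Some further list members and further probes of these genes are given as examples, chosen after their values were seen. Groups, lists, tests and alternatives not named as later additions were set before the data were examined. Alternatives for single genes were run for the probes at least 2-fold on both arrays and those of the fixed set, not for every further probe of these genes, a limit set after the first results. Alternatives were median centring, quantile normalization, keeping probes with a single value, 1 value per gene, a robust prior, no moderation, other thresholds and leaving out each array. The steps were tested on simulated data with noise drawn from limma's fitted spread model and 100 probes changed at each size: over 20 runs on 21427 probes, limma called on average 82.7 of 100 probes changed by 2 on the log2 scale and 1.05 of 100 changed by 1, with 6.1 false calls. The 2-fold rule found 98.9 and 25.2 of them, with 32.6 unchanged probes per run on the same side of both arrays and 37.3 on opposite sides, where the real data had 3 on opposite sides. These averages replaced an earlier single run. By the count on opposite sides the simulated noise had wider tails than these arrays. The calls also depend on how many probes were changed. These rates are therefore not those of the arrays, and 0 calls do not show that large changes are few. In a simulation of 14000 genes, camera with its preset correlation called a list shifted by 0.5 and 1 of 20 unshifted lists, and with an estimated correlation it did not call the shifted list (adjusted p of 0.981). The estimated setting rests on the 1 residual degree of freedom, so a call lost under it does not tell whether a list shifted.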

Results

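Gene expression was compared between murine effector CD8+ T cells after 1 and after 2 rounds of stimulation in culture. The cells came from the pmel transgenic mouse, whose CD8+ T cells carry a receptor for a peptide of the melanocyte protein gp100. Total RNA of the 2 stages was hybridised together on a 2-colour microarray, with the cells after 1 stimulation in channel 1 and the cells after 2 stimulations in channel 2. There were 2 such arrays, the second described as a repeat of the first, and they form the only group of the series. The labels do not say whether the repeat used a new culture or the same RNA, so the errors and limma p-values of single probes and genes measure only the spread between arrays, which may be technical. The camera p-values with a preset correlation set a list against the spread of the other genes. Each value is a log ratio of the 2 channels of a probe. The table held 21919 probes, and 21427 had a value on both arrays. No spot intensities were used here, so the signal behind each ratio is unknown, and the number of arrays limits the precision.

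Which channel is the numerator is not stated in the sources used here. The titles and the channel numbers both put the cells after 1 stimulation first, so a ratio of 1 stimulation over 2 is likely, on that order alone. In that reading a positive value is RNA more abundant after 1 stimulation and a negative value is RNA more abundant after 2 stimulations, and with the opposite order the sides swap. Results are therefore given as the positive and the negative side of the ratio. The log base is not stated either and was taken as 2. If the values are natural logs, each fold given here is too small.

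The 2 arrays ran the same way. Across probes, which are not independent replicates, their log ratios correlated with Pearson's r = 0.494 and Spearman's rho = 0.420. The same sign was seen on both arrays for 62.3% of probes. The standard deviation of the difference between arrays was 0.422, or 0.299 for a single probe on a single array. Array 2 had the wider spread, with an SD of 0.452 over probes against 0.378 on array 1.

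The genes farthest on the positive side were led by Il7r, the receptor chain for the survival cytokine IL-7, and those farthest on the negative side by Bid, a death-promoting BCL2 family member, followed by Socs2, Cdkn2b and then Gzmb, a granzyme (a serine protease of cytotoxic granules). On both arrays and on the same side, 183 probes were at least 2-fold from a ratio of 1, of which 59 were positive and 124 were negative. On opposite sides 3 probes were at least 2-fold on both arrays, and 21.2 of either kind would be met if the arrays were independent. On a single array the counts were 186 positive and 267 negative (array 1, without replicate 2) and 483 and 520 (array 2, without replicate 1), and read as natural logs they would be 237 and 340 on both arrays, an alternative chosen after seeing the data. The positive probes named 41 genes and the negative probes 112 genes. In limma's moderated test no probe of the 21427 passed an adjusted p of 0.05, the smallest adjusted p being 0.162. At an unadjusted p under 0.05 there were 3186 probes, 1471 positive and 1715 negative, against 1071 expected by chance. limma with a robust spread model also called 0 probes, and a test on each probe's own spread called 241, every one of them a probe with identical values on the 2 arrays. Single genes are therefore described by size and by agreement between the arrays, not as called changes. Both arrays had the cells after 1 stimulation in channel 1. If the dyes were also the same, a dye bias of a probe would repeat on both arrays. Agreement between the arrays cannot tell such a bias from a difference in RNA.

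**Figure D1:**
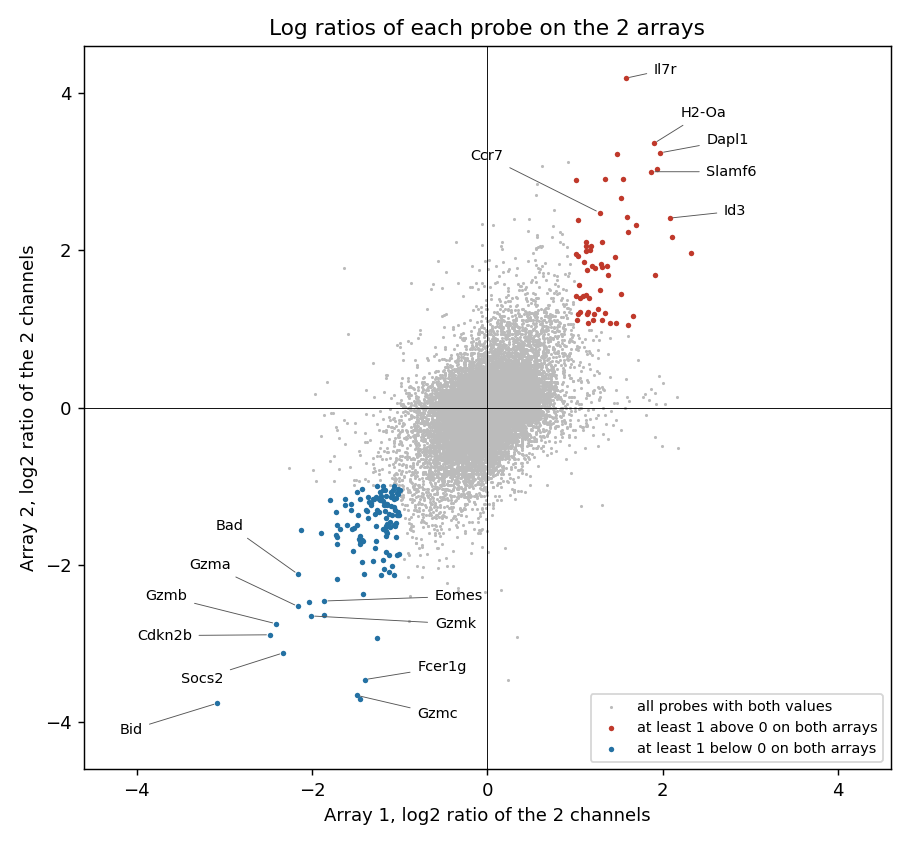
Each point is a probe, with its log2 ratio of the 2 channels on array 1 (x axis) and on array 2 (y axis). The 59 probes at least 1 above 0 on both arrays are red and the 124 at least 1 below 0 are blue, with Il7r and Bid at the far ends.

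On the positive side, Il7r had a mean log2 ratio of 2.89 ± 1.85 (SD, n = 2), a 7.39-fold difference, with 1.58 on array 1 and 4.19 on array 2. H2-Oa, a chain of the class II peptide-loading regulator H2-O, reached 2.63 ± 1.03 (SD, n = 2). Dapl1 followed at 2.61 ± 0.90 and the lymphocyte surface receptor gene Slamf6 at 2.44 ± 0.80 (both SD, n = 2). Smpdl3a read 1.48 and 3.22 on the 2 arrays, the lipid transporter gene Abca3 1.34 and 2.91 and the muscle protein gene Myom1 1.01 and 2.89. A second Abca3 probe gave 0.34 and -0.10. Id3, an inhibitor of E-protein transcription factors, agreed closely between arrays at 2.25 ± 0.23 (SD, n = 2). Tgtp1, an interferon-induced GTPase, stood at 2.01 ± 0.44 (SD, n = 2). The immunoglobulin probes farthest on this side, annotated to Ighm and Ighv6-6, gave 2.15 and 2.14. The other probes of these 2 genes lay nearer 0, and of 32 probes annotated to Ighv6-6 only 1 was at least 2-fold on both arrays.

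On the negative side, Bid stood at -3.42 ± 0.48 (SD, n = 2), a 10.7-fold difference with -3.08 and -3.76 on the 2 arrays. It rests on 1 probe, which lies 2 places from that of Gzma in the order of probe numbers. Socs2, a suppressor of cytokine signalling, was at -2.73 ± 0.56 and Cdkn2b, an inhibitor of cyclin-dependent kinases, at -2.69 ± 0.29 (both SD, n = 2). Pik3cg, a catalytic phosphoinositide 3-kinase subunit of leukocytes, reached -2.26 ± 0.30, the calpain gene Capn10 -2.25 ± 0.55 (both SD, n = 2) and Fcer1g, the Fc receptor gamma chain, -1.40 and -3.46 on the 2 arrays. Bad, another death-promoting BCL2 family member, read -2.16 and -2.12 on 1 probe, next to that of Lmnb1 in probe number (-1.45 and -1.70). For the 12 genes that lead each side, limma's adjusted p lay between 0.162 and 0.222.

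**Figure D2:**
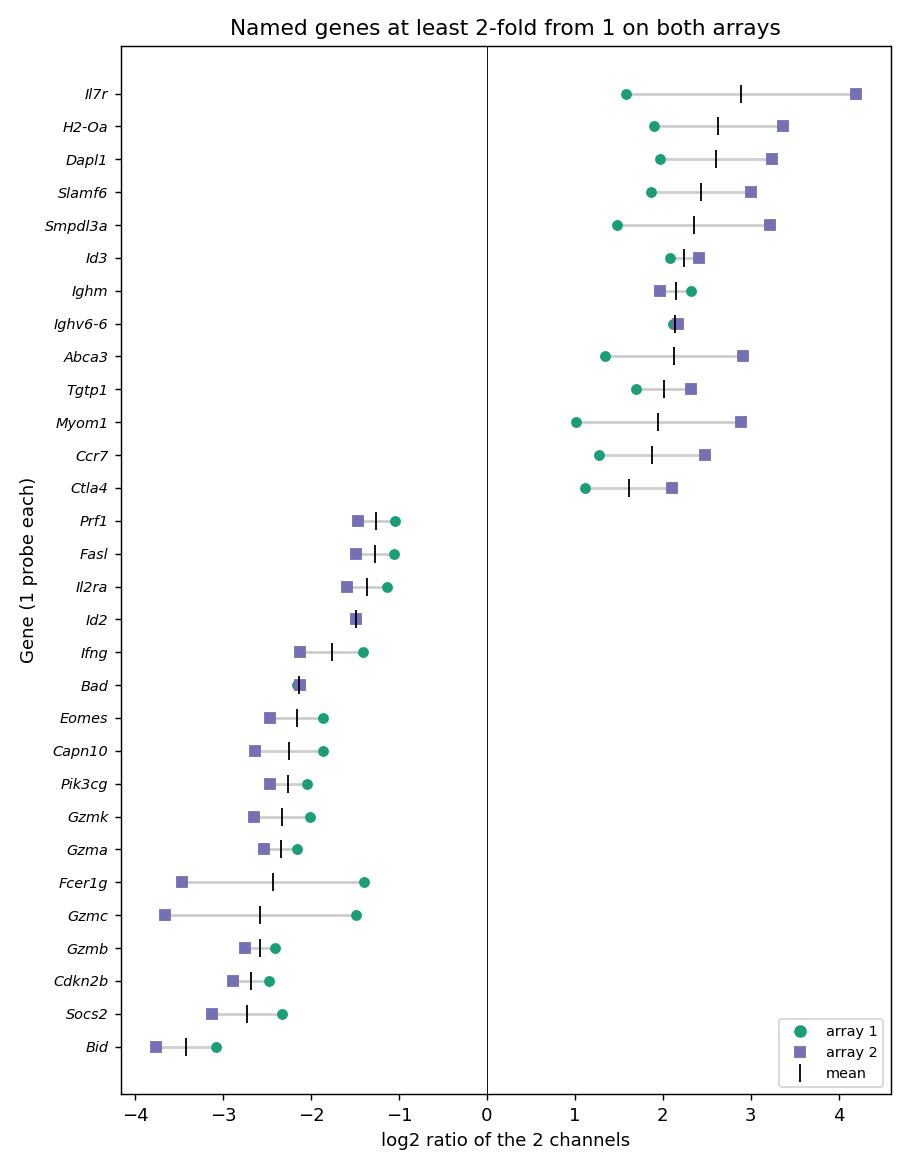
Named genes at least 2-fold from 1 on both arrays, 1 probe each (30 genes on the y axis), with the log2 ratio of the 2 channels on the x axis. Circles are array 1, squares array 2 and bars their mean. Array 2 lies farther from 0 than array 1 for most genes, as for Il7r with 4.19 against 1.58.

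Genes of cytotoxic granules and killing lay together on the negative side. Of 22 measured genes, 18 were negative on both arrays and 0 were positive on both, with a median log2 ratio of -0.576. The granzymes led: Gzmb was at -2.58 ± 0.24 (SD, n = 2), a 5.98-fold difference, Gzma at -2.35 ± 0.26, Gzmk at -2.33 ± 0.45 and Gzmf at -1.95 ± 0.33. Gzmc differed more between arrays, with -1.49 and -3.66. Fasl, the ligand of the death receptor Fas, was at -1.28 ± 0.30 (SD, n = 2). For the pore-forming perforin gene Prf1 the 2 probes disagreed, with means of -1.26 and 0.07. In limma's test 12 of the 22 genes passed when adjusted over the list alone, all on the negative side, and 0 passed over all genes. limma's camera test with its preset correlation placed the list below the other genes at an adjusted p of 4.62e-10. The adjusted p was 0.637 with an estimated correlation, a setting that also missed a simulated shifted list and decides nothing here. Without the granzyme genes the list median was -0.275 and camera's adjusted p 0.000701, a check added after the data were seen. The granzyme genes are close relatives, and the specificity of their probes was not tested.

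Genes of lymphoid homing and of less-differentiated T cells lay on the opposite side from the granzymes. Of 19 measured genes, 15 were positive and 2 negative on both arrays, with a median of 0.450. Beside Il7r and Id3, they included Ccr7, the receptor that guides T cells to lymph nodes, at 1.88 ± 0.85 (SD, n = 2), and the transcription factor gene Myb at 1.33 ± 0.40. The costimulatory receptor gene Cd27 stood at 0.85 and 2.21 on the 2 arrays. Smaller values were seen for Lef1, a transcription factor of naive T cells, at 0.59, Cd28 at 0.47 and Klf2 at 0.32. Bcl2, which protects cells from death, ran the other way at -0.26 and -1.03. Tcf7, also fixed beforehand, had no named probe in the data used here. There were 8 genes that passed when adjusted over the list alone, all positive, and 0 over all genes. B cell markers lay on the same side, with a median of 0.585, or 0.165 without their class II and immunoglobulin genes. For the homing list camera's adjusted p was 5.76e-06, with an adjusted p = 0.637 with an estimated correlation.

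Surface markers and regulators of effector T cells lay mostly on the negative side, with 16 of 28 genes negative and 7 positive on both arrays and a median of -0.368. The T-box factor gene Eomes was at -2.16 ± 0.42 (SD, n = 2). Id2, an inhibitor of E-protein factors like Id3, read -1.49 on both arrays, so the 2 Id genes were on opposite sides. The galectin gene Lgals3 was at -1.60 ± 0.75, Anxa1 at -1.57 ± 0.19 and Anxa2 at -1.12 ± 0.06 (SD, n = 2). Klrg1, a marker of terminal effector cells, was at -0.46 and -2.23. The IL-2 receptor chain Il2rb read -0.42 and -1.18. Of 3 Il2ra probes, 1 was at -1.37 and the others at -0.41 (-0.21 and -0.61 on the 2 arrays) and 0.57 (1.35 and -0.21), so no level is given for that gene. The 2 Cd44 probes likewise disagreed, with 0.31 and 0.18 on the 2 arrays for 1 and -0.29 and -0.84 for the other. Cd69, an early activation marker, was at -0.54, while Tbx21, the gene of the effector factor T-bet, read 0.04 and 0.72. On the positive side stood the integrin gene Itgae, with 0.76 and 2.51 on the 2 arrays, and Klrd1 at 1.16 ± 0.07 (SD, n = 2). Adjusted over the list alone, 12 genes passed on the negative and 2 on the positive side, and 0 passed over all genes. camera's adjusted p was 0.00406, with an adjusted p = 0.637 with an estimated correlation.

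Cell cycle genes gave the lowest median of the 21 lists. Of 43 measured genes, 33 were negative and 1 was positive on both arrays, with a median of -0.830 and -0.840 and -0.780 on the single arrays. Ccna2, the cyclin of DNA synthesis and mitotic entry, stood at -1.53 ± 0.007 (SD, n = 2) and E2f1, a driver of entry into DNA synthesis, at -1.53 ± 0.28. Values for the spindle checkpoint kinase gene Bub1, the proliferation marker Mki67 and the mitotic cyclin gene Ccnb2 were -1.49, -1.43 and -1.39. Rrm2, a subunit of ribonucleotide reductase, was at -1.34 and the primase gene Prim1 at -1.25. Of these genes 26 passed when adjusted over the list alone, all negative, against 0 over all genes. camera's adjusted p was 2.59e-15. With an estimated correlation camera's adjusted p was 0.637. That estimate was -0.019, below the preset 0.01, so correlation between the genes of this list does not account for its lost call. For the cytotoxic, heat shock, respiration, sterol and B cell lists the estimate was above the preset, so there it may.

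**Figure D3:**
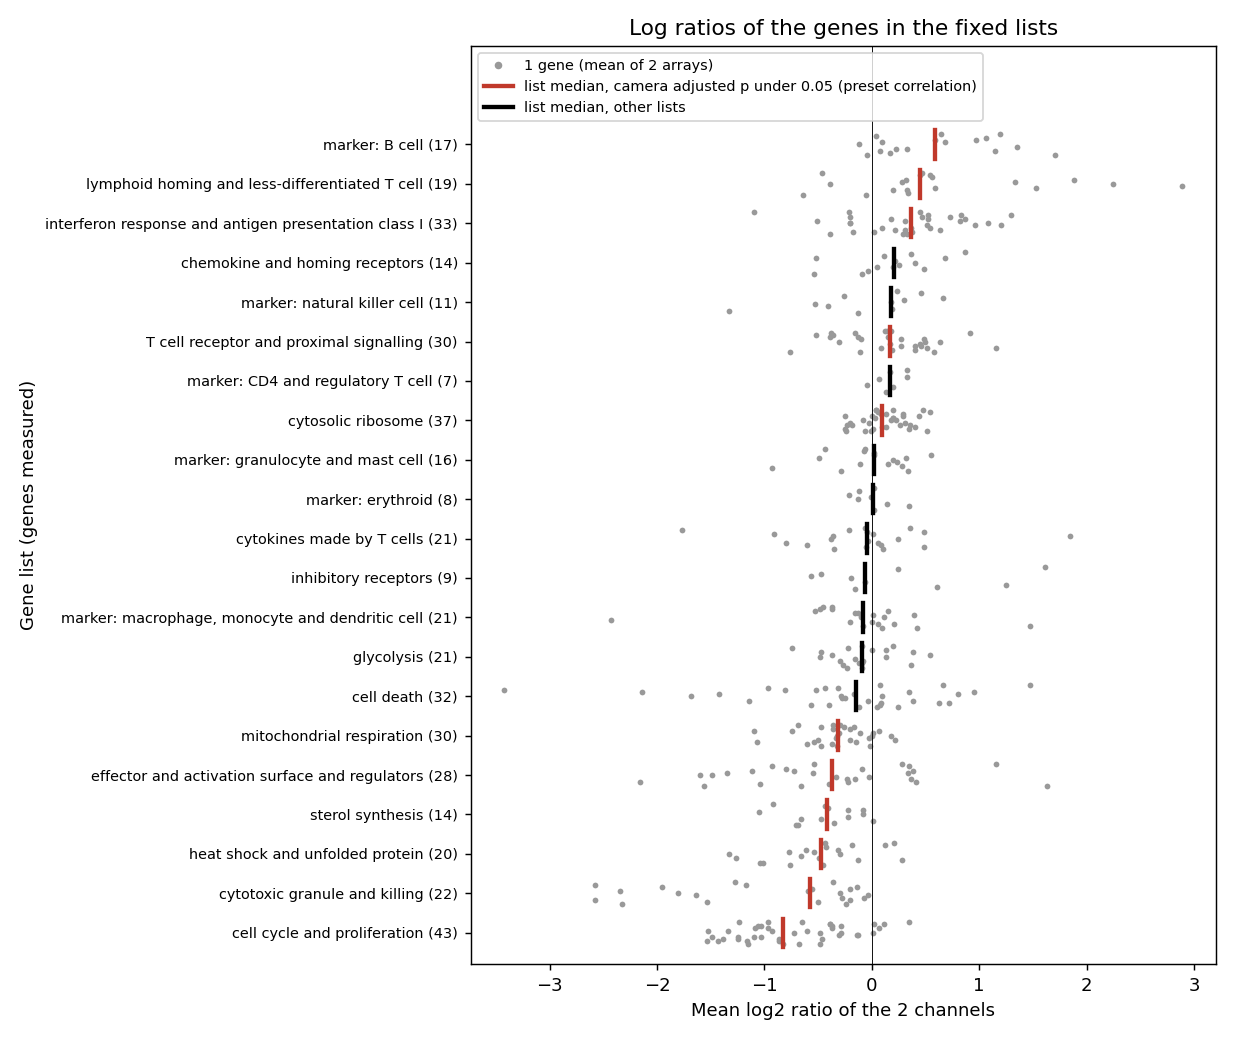
Mean log2 ratio over the 2 arrays (x axis) of each gene in the 21 lists fixed beforehand (y axis, with the number of genes measured). Vertical bars are list medians, red where camera with its preset correlation gave an adjusted p under 0.05. Cell cycle genes have the lowest median, -0.830, and B cell markers the highest, 0.585.

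Cell death genes were found on both sides. Of 32 measured genes, 14 were negative and 9 positive on both arrays, with a median of -0.145, which was -0.075 on array 1 and -0.180 on array 2, and camera gave an adjusted p of 0.286. Beside Bid and Bad, the negative side held Cdkn1a, an inhibitor of cyclin-dependent kinases induced by p53, at -1.69 ± 0.05 (SD, n = 2), the stress gene Gadd45g at -1.42 ± 0.08 and Birc5, which also acts in cell division, at -1.15 ± 0.02. Gadd45b, a relative of Gadd45g, lay on the positive side at 0.86 and 2.08. Bcl2l11, which encodes the death-promoting protein BIM, read 0.01 and -0.80. Adjusted over the list alone, 8 genes passed on the negative and 5 on the positive side, and 0 passed over all genes.

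Several biosynthetic and protein-folding lists lay on the negative side. For sterol synthesis, 12 of 14 genes were negative on both arrays and 0 positive, with a median of -0.420 (camera adjusted p of 4.66e-05). For heat shock and unfolded protein genes, 15 of 20 were negative and 1 positive, with a median of -0.473, which was -0.170 on array 1 and -0.770 on array 2 (camera adjusted p of 3.29e-05), and Pdia6, a disulfide isomerase of the endoplasmic reticulum, stood at -1.33 ± 0.26 (SD, n = 2). For mitochondrial respiration, 20 of 30 were negative and 2 positive, with a median of -0.315, which was -0.155 on array 1 and -0.418 on array 2 (camera adjusted p of 0.000212). The ribosomal protein genes had a small positive median of 0.095 over 37 genes, 15 positive and 3 negative on both arrays (camera adjusted p of 0.0153). B cell markers had a median of 0.585 on that side, or 0.165 without their class II and immunoglobulin genes. camera with an estimated correlation, which also missed a simulated shifted list, passed none of these lists. Its adjusted p was 0.637 for the sterol and ribosome lists, 0.638 for heat shock and 0.651 for respiration. The estimated correlation was 0.338 for respiration, 0.326 for heat shock, 0.235 for B cell markers, 0.121 for sterol synthesis and -0.016 for ribosome. Where it exceeds the preset 0.01, the adjusted p with the preset may be too small, though the estimate rests on 1 residual degree of freedom. The glycolysis genes did not pass the test, with a median of -0.095 over 21 genes, -0.324 on array 1 and 0.090 on array 2 (camera adjusted p of 0.584). In limma's test 4 sterol, 6 heat shock and 2 respiration genes passed when adjusted over the list alone, all negative, with 0 for ribosome and glycolysis and 0 over all genes in each list.

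The list of interferon response and class I presentation genes lay on the positive side, with 18 of 33 genes positive and 6 negative on both arrays. Its median was 0.365, which was 0.210 on array 1 and 0.520 on array 2. The class I presentation genes in it were mixed. B2m (0.12 and 0.54), Tap2 (0.08 and 0.66) and Psmb9 (0.08 and 0.81) were positive on both arrays. H2-K1 (-0.30 and -0.12) and Tapbp (-0.38 and -0.03) were negative on both, and Tap1, Psmb8 and Psmb10 changed sign between arrays. The antiviral genes Isg15 and Oas1a stood at 1.30 ± 0.37 and 1.21 ± 0.02 (SD, n = 2). camera's adjusted p was 3.29e-05, with an adjusted p = 0.637 with an estimated correlation, and 4 genes passed when adjusted over the list alone, against 0 over all genes. B cell markers moved with this list too, with a median of 0.585, or 0.165 without their class II and immunoglobulin genes. Ifng, the gene of interferon gamma itself, lay on the negative side at -1.77 ± 0.50 (SD, n = 2). It was the only T cell cytokine gene at least 2-fold on both arrays. The cytokine list as a whole did not pass the test, with a median of -0.045 over 21 genes (camera adjusted p of 0.657). Its sign turned between arrays, with 0.110 on array 1 and -0.160 on array 2. The lymphotoxin gene Ltb read 0.62 and 3.07, Il2 0.18 and -0.27 and Tnf 0.02 and -0.44. Adjusted over the list alone, 1 of its genes passed, and 0 passed over all genes.

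T cell receptor and signalling genes had a median of 0.173, with 16 of 30 genes positive and 6 negative on both arrays (camera adjusted p of 0.020, and an adjusted p = 0.637 with an estimated correlation). B cell markers lay on the same side, with a median of 0.585 (0.210 and 0.830 on arrays 1 and 2), or 0.165 without their class II and immunoglobulin genes. On the 2 arrays Cd3e read -0.09 and 0.45, 1 Cd8a probe 0.03 and 0.74 and the other 0.71 and 1.06. Chemokine and homing receptors had a median of 0.210 over 14 genes, which was 0.020 on array 1 and 0.475 on array 2 (camera adjusted p of 0.0928). Adjusted over the list alone, 0 genes passed in either list, and 0 passed over all genes. Among 9 inhibitory receptors, Ctla4 was positive at 1.61 ± 0.69 (SD, n = 2), Lag3 read 0.66 and 1.84, and Pdcd1, the gene of PD-1, -0.56 and 0.17. The Entpd1 probes disagreed, with -1.29 and 0.16. The median of these receptors was -0.060, with -0.040 on array 1 and 0.170 on array 2, although their mean was 0.252 and the test pointed up (camera adjusted p of 0.408), with 4 passing when adjusted over the list alone and 0 over all genes.

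Markers of other cell types that a culture could hold were examined in the same way. B cell markers lay on the positive side beside the homing and interferon genes, with 13 of 17 genes positive and 2 negative on both arrays. Their median was 0.585, with 0.210 on array 1 and 0.830 on array 2, a shift larger on the repeat array (camera adjusted p of 3.29e-05, and an adjusted p = 0.637 with an estimated correlation). The class II chain H2-Eb1 read 0.57 and 2.84, and the B cell receptor subunit Cd79b 0.67 and 1.62. Ms4a1 read 0.11 and 0.08 and Pax5 0.21 and -0.06. Without class II and immunoglobulin genes the median of the B cell list was 0.165 over 11 genes. Markers of macrophages, monocytes and dendritic cells had a median of -0.085 over 21 genes (camera adjusted p of 0.839), with Fcer1g at the negative and Ctss, a lysosomal protease, at the positive end with 1.48 ± 0.53 (SD, n = 2). Medians were 0.025 for granulocyte and mast cell markers, 0.008 for erythroid markers, 0.165 for CD4 and regulatory T cell markers and 0.175 for natural killer cell markers, with camera adjusted p of 0.686, 0.839, 0.0928 and 0.869. On arrays 1 and 2 the medians were -0.060 and -0.030 for macrophage, -0.045 and 0.010 for granulocyte, -0.145 and 0.010 for erythroid and 0.06 and 0.20 for CD4 markers. The mean was negative, at -0.016 and -0.058, for the granulocyte and the natural killer lists, whose median and test were positive. For the natural killer list the medians on the single arrays were also negative, at -0.150 and -0.180. Adjusted over the list alone, 1 B cell, 1 macrophage and 2 natural killer markers passed and 0 of the other 3 lists, with 0 over all genes in each.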

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

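The count of 0 called probes held under median centring, quantile normalization, probes kept on a single value, 1 value per gene, a robust prior and an adjusted threshold of 0.10, with smallest adjusted p from 0.0820 to 0.164. It was 3186 at an unadjusted p under 0.05 and 241 without moderation, where all 241 were probes rounded to the same value on both arrays and the smallest adjusted p of the others was 0.185. The 59 positive and 124 negative probes became 373 and 507 at 1.5-fold, 11 and 15 at 3-fold, and 237 and 340 if the values are natural logs (chosen after seeing the data); 1 value per gene, which drops unnamed probes and averages the probes of a gene, gave 33 positive. With a single array in use, the count ranged from 186 to 483 positive and from 267 to 520 negative probes, without replicate 2 and without replicate 1 in that order, since nothing then removes what the other array does not repeat. The 5 positive and 6 negative list calls became 0 and 0 with an estimated correlation (smallest adjusted p of 0.637), and kept their number under the other camera settings run except an adjusted threshold of 0.10, which gave 7 positive and 6 negative. The estimated correlation leaves 1 residual degree of freedom and missed a simulated shifted list, so its result weighs neither for nor against the lists. fry, which tests a list against no change and not against other genes, passed 0 and 0 (smallest adjusted p of 0.0822). All 11 called lists had the same sign of the median on each array alone. A floor and ceiling filter removed 0 probes. Of 73 probes of named genes, 0 turned sign or changed over 1.5 times under centring, quantile normalization or with single-array probes kept. With 1 value per gene 3 turned sign, 1 probe each of Cd44, Il2ra and Prf1, and 11 changed over 1.5 times or turned, among them Ighm (2.15 to 0.97) and Entpd1 (-1.29 to -0.57), because the probes of a gene were averaged. Without replicate 1, 2 turned sign and 10 changed over 1.5 times or turned, and without replicate 2, 4 and 21. Pearson's r lay between 0.494 and 0.519. The list test with single-array probes kept was planned and not run; turning the sign of array 2 was not run because the arrays correlated positively, and the size rule and r with single-array probes, or a test on a single array, have no value. Signal over background is unknown without intensities.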

Other observations

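Further gene groups, picked by symbol after the data were seen, lay on both sides. DNA replication factors not in the cell cycle list had a median log2 ratio of -0.750 over 29 genes, 23 negative and 1 positive on both arrays, with Rfc3, a clamp-loader subunit, at -1.61 and Gins1, of the replicative helicase, at -1.56. Kinetochore and condensation genes had a median of -0.500 over 27 genes, 19 negative and 0 positive, with Cenpk at -1.56. Serine and one-carbon synthesis genes had a median of -0.770 over 8 genes, with Psat1, a serine synthesis enzyme, at -1.54 and Mthfd1, a folate enzyme, at -1.35. Medians were -0.345 for 39 proteasome subunits (-0.140 and -0.440 on arrays 1 and 2), -0.345 for 9 chaperonin subunits (-0.235 and -0.740) and -0.263 for 18 aminoacyl-tRNA synthetases. On the positive side, 5 Schlafen genes had a median of 1.12 (0.57 and 1.44 on arrays 1 and 2), 3 positive and 1 negative on both arrays. Among them Slfn2, a gene tied to T cell quiescence, read 0.57 and 2.17. The 12 genes of class II and its loading had a median of 1.04 (0.40 and 1.70), 11 positive and 0 negative on both arrays. Of 10 such groups 9 were tested, and all but the killer cell lectin-like receptors (median 0.105, but -0.10 and 0.06 on arrays 1 and 2, adjusted p of 0.432) passed camera with its preset correlation, with adjusted p from 1.21e-11 to 0.0136, and none passed with an estimated correlation (adjusted p = 0.414 to 0.542). The estimated setting also missed a simulated shifted list, so it decides nothing about these groups. Because the groups were picked after the data were seen, passing with the preset correlation is not independent support either.

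The tests of Bid and Bad against their neighbours and the comparison of class II with immunoglobulin probes were chosen after the results were seen; the other tests were set before the value they measure was seen, but after a first look at the 50 leading probes of each side and at the fixed genes, which showed some of their members, among them Bid, Bad, Fcer1g, Ctss, Cdkn1a and class II and immunoglobulin probes. These 2 genes' own tests were added when the test of all neighbours had left carry-over open.

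Most class II genes lay on the positive side, as did 4 immunoglobulin probes with a mean of at least 1. Some other immunoglobulin probes had smaller positive values on both arrays, such as Ighm probes at 0.33 and 0.27 and at 0.43 and 0.41. Further ones were negative on both arrays, and the sides of all immunoglobulin probes were not counted. Macrophages or dendritic cells in the RNA of the positive side were predicted to raise their markers by at least 0.5. The median of 21 such markers was -0.085 (-0.0925 to -0.040 leaving out any 1), with 4 positive and 8 negative on both arrays. This argues against a general rise of these markers. A few such cells are not excluded, since the signal of each marker is unknown and Ctss read 1.10 and 1.85. B cells remain possible: 11 B cell markers that are neither class II nor immunoglobulin had a median of 0.165 (0.130 to 0.248 leaving out any 1, and 0.110 and 0.320 on arrays 1 and 2), between the 2 predictions. On the 2 arrays Cd79b read 0.67 and 1.62 and Cd79a 0.31 and 1.06, but Ms4a1 0.11 and 0.08 and Pax5 0.21 and -0.06. From array 1 to array 2 a set of 11 class II genes moved by a median of 1.36 and the 4 immunoglobulin probes with a mean of at least 1 by -0.01, a difference of 1.37 (exact two-sided permutation test over 1365 splits, p = 0.220), but these probes were picked by their own mean and the class II genes were not, so this comparison decides nothing about B cells as the only source. A change in class II expression within the T cells was not tested and stays open.

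Bid and Bad were among the probes farthest on the negative side, but each rests on a single probe and, in the order of probe numbers, Bid lies 2 places from Gzma (-2.16 and -2.53) and Bad next to Lmnb1 (-1.45 and -1.70). Mixing with a neighbouring spot would give a ratio between those of the 2 spots. Bid lay beyond Gzma, the most negative probe within 6 places, by -0.92 and -1.23 on the 2 arrays, a mean of -1.075 against an SD of 0.299 for such a difference. But Bid was singled out as the lowest probe of both arrays (-3.08 and -3.76), and whether probe numbers follow the places of the spots is not known. The test therefore does not exclude carry-over as the only cause for Bid. Carry-over also stays open for Bad, which lay beyond Lmnb1 by -0.71 and -0.42, a mean of -0.565 and less than 2 such SDs. For the array as a whole it stays open too. Next to 90 probes at least 1.5 from 0, probes 1 or 2 places away lay toward them by 0.050 more than probes 10 to 20 places away (95% bootstrap interval 0.010 to 0.095). That excess was smaller than predicted for carry-over and met neither prediction. Genes of like function can also lie close in probe number, as the cell division genes Birc5 and Bub1 do near Bad. Such an excess therefore does not show carry-over. The other 30 cell death genes had a median of -0.080 (-0.120 to -0.040 leaving out any 1, and -0.060 and -0.075 on arrays 1 and 2) with members on both sides (camera p of 0.670). By the bounds set beforehand the test could not decide, since the range leaving out any 1 went past the bound for no group shift. The median lay far from the values of Bid and Bad, so the list did not share a shift of their size. A smaller group shift stays open. A probe printed in the wrong place, or a true difference in Bid and Bad, was not tested.

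Probes of different genes 2 and 96 places apart in probe number had correlated mean log ratios (r of 0.149 and 0.150, across probes), the 2 highest of 37 distances examined, against 0.042 at 3 places and 0.032 at 100 places, which were picked after the values were seen. The difference between the 2 arrays showed 0.121 and 0.145 at 2 and 96 places, against 0.051 and 0.023. For the mean the other distances lay between, such as 48 places with 0.129. For the difference some lay lower than at 100 places, such as 48 places with 0.014 and 28 places with -0.013. Of the 344 probes measured on a single array, 12 were at least 1 above 0 and 1 was at least 1 below 0.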
